A study of Mus musculus with 4 samples.

How the data were processed

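RNA was measured by sequencing in 4 libraries of mouse ovary, 2 from animals carrying an oxytocin receptor transgene (OxtrTg) and 2 from wild-type animals (WT). Per the labels, libraries were prepared with the NEBNext Ultra II RNA kit from total RNA. The labels give ovary as the source and the tissue of every library, while their RNA extraction protocol names white adipose tissue. That difference is left as the labels have it, and it bears on the adipocyte genes reported here. Per the series design text, the females were in diestrus, a phase of the estrous cycle.

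The deposited table holds 21958 gene rows with 2 values per library. Per the file headers, the first value is a read count, and these counts are whole numbers that were not normalised. Per the file headers, the second value is FPKM, and it equals the count divided by the deposited gene length (the table's own Length column, in bases) and by the library's total count. The genome build mm10 is named in the submitters' processing notes. The aligner, the counting program, its strand setting and the gene annotation are not given in the sources used here. Of the gene identifiers, 21850 were found in GENCODE release M21, which is on the GRCm38 build. All 100% of these had the same chromosome there, and 2.35% had the same start and end. The positions printed here are therefore those of the deposited table, whose build the table does not name, and none were taken from the reference. Of the matched identifiers, 99.4% were annotated as protein coding. A gene symbol was lacking in 51 rows, which stayed in the tests under their identifiers.

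Groups were taken from the sample titles, and the replicate numbers (3 and 4 for OxtrTg, 5 and 6 for WT) are those of the titles. No number is shared between groups, so the libraries were not paired. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Library totals were 15229810 and 15319853 counts for OxtrTg replicates 3 and 4, and 16517764 and 16105024 for WT replicates 5 and 6. A count of 0 allows up to 3 counts, which is 0.182 to 0.197 CPM (counts scaled to library size) per library. Intervals (95%, exact conditional binomial) and these floors cover counting error only. The counts of replicates of a group differed by more than sampling noise (chi-square over degrees of freedom 45.1 between the OxtrTg libraries and 42.9 between the WT libraries). No pair was thus 1 library deposited again, which does not show that the libraries came from separate animals.

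The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM scaling and the filterByExpr filter with its minimum count of 10, which left 15311 genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 and no fold threshold. Fold changes are given on the log2 scale with the standard error (SE) of the fit, and levels as TMM-scaled CPM with the standard deviation (SD) over 2 libraries. The common dispersion was 0.104, with 2 residual degrees of freedom. The 29 gene lists, with 424 distinct genes in the table, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with p-values adjusted over the 29 lists. Camera with an estimated correlation and fry were run beside it. A list's members were also counted with p-values adjusted over the list alone. The lists overlap, so that Lpl, for example, is counted among both adipocyte markers and lipid genes.

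The rule for named genes took Oxtr, then the 12 genes with the smallest adjusted p in each direction that passed the threshold by at least 2-fold with both libraries of a group on the same side. It passed over predicted genes. From each list it took up to 4 members past the threshold or, where none passed, the 2 members with the highest mean level. It added 16 fixed genes of prolactin signalling, gonadotrophin response and steroid synthesis, of which 15 are reported and 1 is not used here. No gene passed the main test, so after the values were seen the same rule was applied to the calls of DESeq2, which named 12 genes higher and 2 lower. Any other gene named in the text was chosen after its values were seen.

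Alternatives were DESeq2 1.42.0 (Wald test), limma-voom, other scalings (DESeq2 size factors, total counts alone, upper quartile), no filter or a CPM above 1 in 2 libraries, other thresholds, limma with trend on log2(FPKM + 1) for genes with a mean FPKM of at least 1, the same with a pseudocount of 0.1 or without that filter, and each library left out in turn. Leaving libraries out of DESeq2 and counting its calls without adipocyte genes were added after the data were seen. The tests were checked on simulated counts with the means, library sizes and spread of these libraries and 50 genes changed at each of 4 fold sizes. For OxtrTg against WT, edgeR recovered 26% of genes changed 2-fold, 74% at 4-fold, 88% at 8-fold and 90% at 16-fold, with 12 false calls among 15311 genes. DESeq2 recovered 54%, 88%, 96% and 90% at the same fold sizes, with 81 false calls. Each gene was drawn independently, so differences between libraries that many genes share were not simulated. These shares therefore may not hold for the real counts, where Cfd, with a ratio of 9.16, did not pass edgeR (adjusted p = 0.177).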

Results

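Transcript levels were measured in whole ovaries of mice that overexpress the oxytocin receptor (OxtrTg, replicates 3 and 4) and of wild-type mice (WT, replicates 5 and 6). The series asks which genes differ in OxtrTg ovaries, as a way into how the receptor acts on follicle development, and its title names prolactin and STAT3 signalling. Each library held 15229810 to 16517764 counts over 17135 to 17365 genes. Mitochondrially encoded genes took 2.43% to 3.06% of the counts. OxtrTg replicate 4 and WT replicate 5 were the most alike of all pairs across genes (Spearman 0.984), above the pair of OxtrTg libraries (0.954) and the pair of WT libraries (0.975).

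Oxtr (ENSMUSG00000049112), the gene of the oxytocin receptor, stood at 110 and 161 CPM in OxtrTg replicates 3 and 4, and at 29.2 and 55.5 CPM in WT replicates 5 and 6. The means were 135 ± 36.6 CPM in OxtrTg and 42.4 ± 18.6 CPM in WT (SD, n = 2 each), a ratio of 3.20. Both OxtrTg libraries lay above both WT libraries, in the order the labels give. In the deposited FPKM values the levels were 23.2 and 32.9 against 6.21 and 11.5. The gene lies on chromosome 6, minus strand, from 112450644 to 112466904 in the deposited table. The log2 difference was 1.68 ± 0.39 (SE), with an unadjusted p of 0.0103 and an adjusted p of 1 in edgeR's quasi-likelihood test, so the difference did not pass over all genes. DESeq2 called it, with an adjusted p of 0.00611. With each library left out in turn, DESeq2 called it in 3 of 4 fits, and lost it without OxtrTg replicate 4 (adjusted p = 0.0539).

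**Figure D1:**
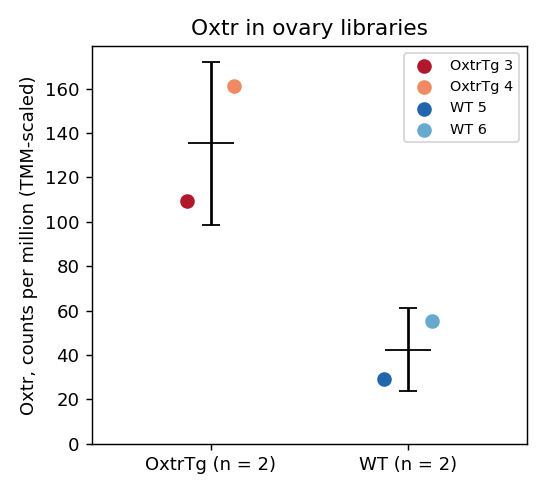
Oxtr level in TMM-scaled CPM (vertical axis) in each OxtrTg and WT library (points), with the group mean (horizontal bar) and SD (error bar, n = 2). The OxtrTg libraries sit at 110 and 161, and the WT libraries at 29.2 and 55.5.

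Cfd, Cidec, Acsl1 and Pnpla3, genes of fat cells and of fat synthesis, had the smallest p of all genes, with more transcript in OxtrTg. Cfd, which encodes the adipocyte product adipsin, was at 279 ± 27.4 CPM in OxtrTg and 30.5 ± 2.54 CPM in WT (SD, n = 2 each), a ratio of 9.16. Adipoq (adiponectin) was at 89.7 ± 33.9 against 8.09 ± 0.426 CPM, Fabp4 (a fatty acid carrier) at 330 ± 113 against 31.5 ± 1.52, and Cidec (a lipid droplet protein) at 89.4 ± 15.7 against 9.65 ± 0.15. Scd1, which desaturates fatty acids, was at 1256 ± 447 against 80.3 ± 10.8 CPM, a ratio of 15.7. With p-values adjusted over the list alone, 12 of 15 adipocyte markers and 7 of 18 genes of lipid storage and fatty acid metabolism rose in OxtrTg. Over all genes tested none of them passed in edgeR, where Cfd had the smallest adjusted p of any gene, 0.177.

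The 12 adipocyte markers that rose over the list alone were Cfd, Cidec, Fabp4, Car3, Lpl, Adipoq, Retn, Lep, Pnpla2, Adrb3, Plin1 and Lipe. Car3 (carbonic anhydrase 3) was at 898 and 631 CPM in the OxtrTg libraries and 82.9 and 58.8 in the WT libraries. The hormone genes Retn (resistin) and Lep (leptin) had ratios of 14.0 and 13.5, and Lpl, which releases fatty acids from lipoproteins, a ratio of 3.48. Pparg, the regulator of fat cell differentiation, was at 39.3 ± 0.945 against 28.6 ± 8.35 CPM and did not pass, nor did Plin4 and Cidea. The list had a median log2 difference of 3.09, and 13 of its 15 members were higher in both OxtrTg libraries than in both WT libraries. Camera placed it above other genes (adjusted p = 5.9e-26), while it had an adjusted p = 0.791 with an estimated correlation. Fry gave an adjusted p of 0.187 for one direction and of 0.0495 for change in either direction. Leaving out each library in turn kept the camera call, with adjusted p from 4.0e-24 to 3.1e-12.

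Among lipid genes, those that rose over the list alone were Fasn, Scd1, Lpl, Acaca, Cd36, Dgat2 and Dgat1, which serve fatty acid synthesis, uptake and triglyceride assembly. Fasn (fatty acid synthase) was at 833 ± 75.4 CPM in OxtrTg and 266 ± 5.02 in WT, and Dgat2 at 149 ± 27.3 against 26.1 ± 14.7. Members that did not pass over the list alone included Cpt1a at 204 against 224 CPM, Hadha at 254 against 284 and Acadm at 134 against 128. Scd2, the second desaturase and a highly expressed member, was at 1039 ± 308 against 1198 ± 97.7 CPM. The list passed camera (adjusted p = 4.2e-06), with an adjusted p = 0.834 with an estimated correlation. Without WT replicate 5 the camera call was lost (adjusted p = 0.187).

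Over all 15311 genes tested, edgeR called 0 genes higher and 0 lower in OxtrTg, and limma-voom also called 0 in each direction. At an unadjusted p under 0.05, edgeR gave 324 genes higher and 69 lower, 393 in all, where 766 are expected by chance. The series design text reports differentially expressed genes in both directions, by a test and threshold not given in the sources used here. DESeq2 called 66 genes higher and 3 lower, 57 of them by at least 2-fold. Its calls included 11 adipocyte markers and 6 lipid genes, together with Oxtr. In the simulated counts with the spread of these libraries, DESeq2 made 81 false calls. Beside them it called 27, 44, 48 and 45 of the 50 genes changed at each fold size. The share of false calls was thus above the threshold of 0.05, and its adjusted p may understate that share. The number of false calls depends on how many genes change, so 81 cannot be set against the 69 calls made here. By the naming rule, the genes it called higher were Cfd, Scd1, Cidec, Car3, Acsl1, Fasn, Fabp4, Lpl, Adipoq, Pnpla3, Cdo1 and Trf, with DESeq2 adjusted p from 8.0e-66 (Cfd) to 9.4e-15 (Trf). Acsl1 (acyl-CoA activation) had a ratio of 4.75, Pnpla3 (a lipid droplet lipase) of 10.7, Cdo1 (cysteine dioxygenase) of 4.58 and Trf (transferrin) of 3.94. With OxtrTg replicate 4 left out, edgeR called 7 genes higher and 58 lower. DESeq2 called 44 to 82 higher and 2 to 421 lower over the 4 fits that each left out 1 library, with 421 lower without OxtrTg replicate 4, 77 lower without WT replicate 5 and 8 lower without OxtrTg replicate 3.

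The 3 genes DESeq2 called lower were Gsg1l, Zfp970 and Gm14403. Gsg1l, an auxiliary subunit of glutamate receptors, was at 4.73 and 4.68 CPM in the OxtrTg libraries and 23.5 and 23.4 CPM in the WT libraries (log2 difference -2.32 ± 0.22, DESeq2 adjusted p = 8.7e-11). It lies on chromosome 7 from 125477592 to 125681583. Zfp970, a zinc finger gene on chromosome 2 from 177156526 to 177169922, had 3 counts over both OxtrTg libraries and 368 over both WT libraries, a WT to OxtrTg ratio of 114 (95% interval 38.7 to 555). Gm14403, a predicted gene named here because only 3 genes were called lower, begins at 177190008 on the same chromosome. It had 0 against 106 counts, 32.8-fold lower in OxtrTg with a floor of 3 counts over the group (exact 95% lower limit 26.2-fold). Both sit in a cluster of closely related zinc finger genes, so the counts of each are uncertain where reads fit more than 1 member. Leaving out each library in turn, DESeq2 kept Zfp970 in 4 of 4 fits and Gsg1l in 3, losing it without WT replicate 6 (adjusted p = 0.095). It kept Gm14403 only without OxtrTg replicate 4 (adjusted p = 0.0212), with 0.136 without OxtrTg replicate 3 and no adjusted p without either WT library, where DESeq2's own filter on low counts set the gene aside. In edgeR the adjusted p was 0.353 for Gsg1l, 0.272 for Zfp970 and 0.803 for Gm14403.

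Genes of connective tissue and vessels stood higher in OxtrTg as lists. Of 20 extracellular matrix genes, 17 had a positive log2 difference and 13 were higher in both OxtrTg libraries than in both WT libraries. Col3a1 was at 2806 ± 467 against 2151 ± 265 CPM and Col1a2 at 2714 ± 690 against 1907 ± 281. DESeq2 called 2 members, Lum (a collagen-binding proteoglycan, 580 ± 8.92 against 303 ± 61.7 CPM) and Lox (a collagen and elastin crosslinker, 119 ± 22.5 against 59.0 ± 3.10). In edgeR 0 members passed over all genes and 0 adjusted over the list alone, as for each list described from here on. Camera gave the list an adjusted p of 3.9e-05, with an adjusted p = 0.834 with an estimated correlation, and 0.0797 without OxtrTg replicate 4. Of 13 endothelial and pericyte markers, 9 were higher in both OxtrTg libraries, among them Pecam1 (146 ± 9.80 against 102 ± 11.1 CPM), while the pericyte gene Pdgfrb was at 114 ± 4.67 against 151 ± 31.8. That list had an adjusted p of 5.4e-04 in camera, an adjusted p = 0.791 with an estimated correlation, and a fry p for either direction of 0.0311. Its camera call held without each library in turn (0.0113 to 0.0298). The median log2 deviation of the matrix list from its 4-library mean was 0.00157 in OxtrTg replicate 3 and 0.386 in replicate 4. In WT replicates 5 and 6 it was -0.184 and -0.171. The endothelial and pericyte list had 0.12 and 0.11 in the OxtrTg libraries, and -0.11 and -0.18 in the WT libraries. The adipocyte list, at 1.70 and 1.31 in OxtrTg replicates 3 and 4, thus did not share the matrix list's pattern within OxtrTg. Whether these lists move together was not tested.

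Blood and immune cell genes varied between the 2 libraries of each genotype. Of 16 macrophage markers, 14 had a positive log2 difference, with a median of 0.42. Lyz2 was at 367 ± 142 against 274 ± 116 CPM and Mpeg1 at 94.3 ± 21.8 against 101 ± 15.6. Camera gave that list an adjusted p of 8.0e-05, with an adjusted p = 0.834 with an estimated correlation, and 0.0772 without OxtrTg replicate 3 or 0.19 without WT replicate 6. Of 6 red cell markers, 5 were positive, and the haemoglobin gene Hbb-bs ran from 135 CPM in OxtrTg replicate 3 to 16.1 CPM in WT replicate 6, while Bpgm was at 69.9 ± 25.4 against 76.5 ± 11.5 CPM. The red cell list (adjusted p = 8.6e-04, and adjusted p = 0.834 with an estimated correlation) had an adjusted p of 0.168 without OxtrTg replicate 3. Lymphocyte markers lay lower in OxtrTg in camera (adjusted p = 0.0093, and adjusted p = 0.933 with an estimated correlation), with Cd4 at 16.7 CPM in WT replicate 5 and 3.89 to 6.87 in the other 3 libraries, and Lck at 5.89 ± 2.38 against 10.1 ± 5.45. Without WT replicate 5 their direction turned and the adjusted p was 0.696, and without OxtrTg replicate 4 it was 0.827. Interferon response genes also lay lower (adjusted p = 7.6e-04, and adjusted p = 0.834 with an estimated correlation), with 16 of 18 members negative, a median of -0.19, and an adjusted p of 0.231 without WT replicate 5. Their most abundant members, Bst2 (164 ± 32.1 against 182 ± 22.1 CPM) and Stat2 (84.3 ± 10.1 against 87.2 ± 1.90), were close in level.

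Steroid hormone genes were set apart in 1 WT library. Cyp11a1, which makes pregnenolone from cholesterol, was at 553 and 411 CPM in the OxtrTg libraries, 253 in WT replicate 5 and 3559 in WT replicate 6. Star, which carries cholesterol into mitochondria, was at 50.5 and 45.0 CPM in OxtrTg, 42.8 in WT replicate 5 and 257 in WT replicate 6. Hsd3b1 (1600, 1557, 1794 and 3640 CPM, in the same order), Cyp17a1 (74.9, 100, 56.6 and 307) and Lhcgr, the receptor of luteinising hormone (144, 216, 48.8 and 513), were also highest in WT replicate 6. Cyp19a1, the aromatase gene that makes estrogens, was at 23.8 and 73.2 CPM in OxtrTg and 8.57 and 63.2 in WT. Akr1c18, which breaks down progesterone in the corpus luteum, had 6, 3 and 9 counts in the first 3 libraries and 4016 in WT replicate 6, and was removed by the filter.

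As lists, steroid hormone synthesis (12 of 15 members negative) and luteal cell markers (12 of 12 negative) lay lower in OxtrTg in camera. Their adjusted p were 0.0093 and 0.00444, with an adjusted p = 0.882 and an adjusted p = 0.834 with an estimated correlation. Both turned direction without WT replicate 6 (adjusted p 0.131 and 0.162), and steroid synthesis had 0.0639 without OxtrTg replicate 3. Without OxtrTg replicate 4 they stood at 0.19 and 0.0816. Cholesterol synthesis and uptake also lay lower (17 of 20 negative, median -0.45, adjusted p = 5.4e-04, and adjusted p = 0.834 with an estimated correlation), with Hmgcs1 at 113 ± 4.76 against 168 ± 60.2 CPM and Srebf2 at 130 ± 41.4 against 164 ± 17.1. It had an adjusted p of 0.37 without WT replicate 6 and 0.154 without OxtrTg replicate 3. Theca and interstitial markers, which share Hsd3b1, Cyp11a1 and Star with these lists and include Aldh1a1 (800 ± 345 against 1631 ± 1312 CPM), did not pass (adjusted p = 0.318).

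Oviduct epithelium markers as a list were far lower in OxtrTg replicate 3 than in the other 3 libraries, with a median log2 difference of -3.85. Ovgp1, the oviduct glycoprotein, was at 15.9 CPM there and at 2576, 1974 and 582 CPM in OxtrTg replicate 4 and WT replicates 5 and 6. Dnah5, a motor of cilia, was at 0.777 CPM there against 163, 148 and 141. The list lay lower in OxtrTg in camera (13 of 15 negative, adjusted p = 0.00218, and adjusted p = 0.882 with an estimated correlation). Without OxtrTg replicate 3 its direction turned, with an adjusted p of 0.442, and without WT replicate 5 it was 0.247. The same library had the lowest smooth muscle levels, with Acta2 at 851 CPM against 1838, 1411 and 1062, and Myh11 at 632 against 1610, 1241 and 801. It also had the highest oocyte levels, with Padi6 at 229 CPM against 115, 164 and 161. Neither the smooth muscle list nor the oocyte list passed between genotypes (adjusted p = 0.9 and 0.979).

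**Figure D2:**
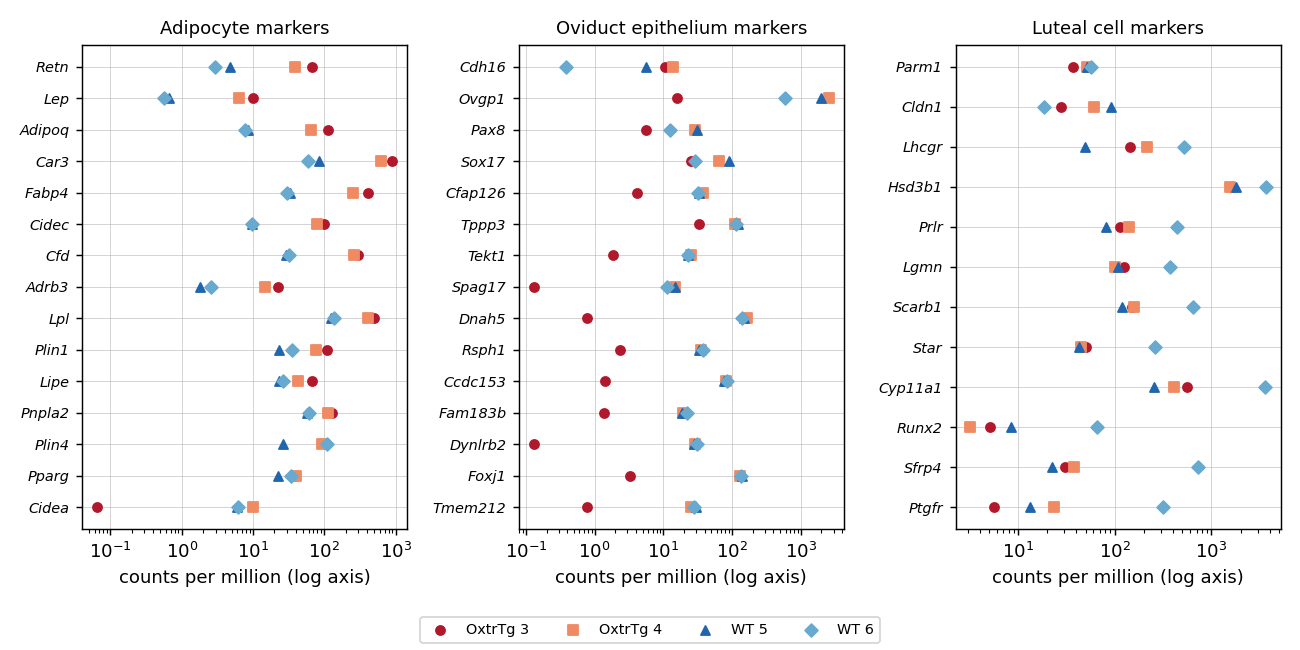
Levels of adipocyte, oviduct epithelium and luteal cell markers in TMM-scaled CPM (horizontal log axes), with a point for each library and a row for each gene tested. Adipocyte genes such as Adipoq separate the genotypes, Dnah5 and most oviduct genes separate OxtrTg replicate 3, and Cyp11a1 and most luteal genes separate WT replicate 6.

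Genes of prolactin signalling and of the STAT3 response, which the title of the series names, did not pass as lists. Prl, the gene of prolactin, had 0 counts in every library, which allows up to 0.182 to 0.197 CPM, and Oxt, the gene of oxytocin, had 0, 0, 3 and 1 counts. Prlr, the prolactin receptor, was at 127 ± 20.7 CPM in OxtrTg and 258 ± 250 in WT, where WT replicate 6 alone held 435 CPM. Stat3 was at 195 ± 16.8 against 187 ± 14.8 CPM, a log2 difference of 0.06 ± 0.12 (SE). Its target Socs3 was at 24.1 ± 4.68 against 23.5 ± 4.40, Cish at 5.82 ± 3.22 against 7.52 ± 1.97 and Socs2 at 228 ± 16.8 against 238 ± 8.01. Of 13 oxytocin and prolactin signalling genes, DESeq2 called Oxtr alone, and camera gave the list an adjusted p of 0.914. The STAT3 response list had an adjusted p of 0.733, with Mcl1 at 214 ± 15.1 against 221 ± 13.7 CPM and Il4ra at 104 ± 26.0 against 69.7 ± 10.8. Of its 19 members, 5 were higher in both OxtrTg libraries than in both WT libraries, among them Il4ra and Lrg1 (5.25 and 4.94 against 2.26 and 2.51 CPM). Avpr1a, a vasopressin receptor on the oxytocin list, was at 2.01 and 9.22 against 0.773 and 0.502 CPM. These transcript levels do not measure STAT3 phosphorylation.

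Follicle genes did not pass as lists. Granulosa cell markers had a median log2 difference of 0.05 (adjusted p = 0.979), with Gja1 at 2046 ± 55.5 against 1919 ± 341 CPM and Inha at 1210 ± 171 against 1363 ± 243. Fshr, the receptor of follicle-stimulating hormone, was at 20.1 ± 0.632 against 21.8 ± 4.46 CPM. Amh, made by growing follicles, was at 161 ± 70.1 against 143 ± 19.5. Hormone receptors as a list, with Esr1 at 232 ± 156 against 247 ± 132 CPM, had an adjusted p of 0.318. The oocyte gene Nlrp14 was at 153 ± 60.5 against 132 ± 13.1 CPM. Ovulation genes (adjusted p = 0.733), such as Rgs2 at 382 ± 110 against 334 ± 37.3 CPM and Cited2 at 130 ± 8.52 against 154 ± 68.5, did not pass. Cell cycle genes did not pass (adjusted p = 0.118), with Mki67 at 142 ± 10.4 against 163 ± 19.6 and Ccnd2 at 201 ± 8.03 against 209 ± 48.3.

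The remaining lists did not pass camera either. Surface epithelium markers had an adjusted p of 0.0601, with Upk3b at 198 ± 47.0 against 88.7 ± 36.3 CPM and Krt19 at 137 ± 79.3 against 104 ± 64.6. Insulin and IGF signalling had 0.0536, with Igfbp5 at 1357 ± 86.8 against 1072 ± 106 CPM and Igfbp4 at 448 ± 9.72 against 365 ± 73.3. Apoptosis and atresia had 0.879, with Clu at 647 ± 109 against 785 ± 362 CPM. Cytokines and chemokines (0.979), with Nos2 at 96.2 ± 30.4 against 95.5 ± 20.4 CPM and Il33 at 14.8 ± 2.94 against 11.0 ± 4.76, did not pass. Neutrophil markers (0.979) ran from 1.49 CPM of Ltf and 1.36 of S100a9 in OxtrTg replicate 3 to 140 and 25.7 in WT replicate 5. Immediate early genes had 0.691, with Jun at 112 ± 46.6 against 120 ± 13.3 CPM and Egr1 at 88.9 ± 40.5 against 72.3 ± 29.1. Skeletal muscle markers had 0.879, with a median log2 difference of -0.39, Tnnt3 at 5.46 ± 0.491 against 3.23 ± 0.395 CPM and Atp2a1 at 1.64 ± 0.802 against 2.68 ± 1.18. Mitochondrially encoded genes had 0.733, with mt-Co1 at 12950 ± 1013 against 12320 ± 2025 CPM and mt-Cytb at 4599 ± 425 against 4494 ± 762.

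**Figure D3:**
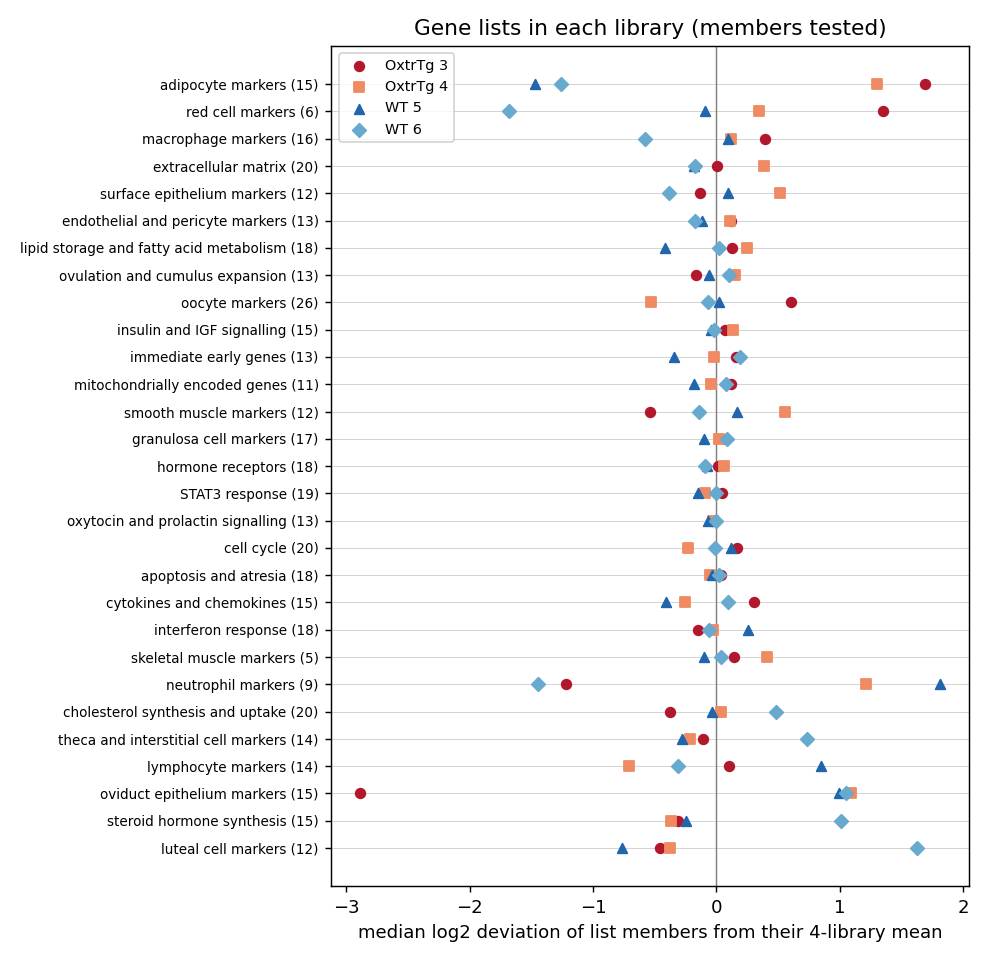
Median log2 deviation of each list's members from their mean over 4 libraries (horizontal axis), with a point per library and the number of members tested in brackets after each list name. The adipocyte list sits at 1.70 and 1.31 in OxtrTg replicates 3 and 4 and at -1.47 and -1.26 in WT replicates 5 and 6.

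In all, 12 of the 29 lists passed camera with the preset correlation, 6 higher and 6 lower in OxtrTg, and 0 passed with an estimated correlation. Fry called 0 lists in 1 direction (smallest adjusted p 0.187) and 3 for change in either direction, those of adipocyte, lipid and endothelial genes. Median and test differed in sign for the oxytocin and prolactin list (median -0.03), smooth muscle (0.06), cytokines (-0.12) and skeletal muscle (-0.39). Mean and test differed in sign for hormone receptors (mean -0.08), smooth muscle (0.059), cytokines (-0.21) and skeletal muscle (-9.1e-04).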

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

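Leaving libraries out of DESeq2, and its counts with a fold threshold or without adipocyte genes were chosen after the data were seen, and the other alternatives before. The log2 difference of Oxtr kept its direction under every alternative run (1.28 to 2.21 with 1 library left out), and passed over all genes in DESeq2 alone (1.67, adjusted p = 0.00611, against adjusted p from 0.485 to 1 in the other tests and leave-outs). With each library left out, DESeq2 gave Oxtr adjusted p from 5.4e-06 to 0.0539, and lost it without OxtrTg replicate 4. At an unadjusted p under 0.05 and at least 2-fold it also passes (1.68). The edgeR counts of 0 higher and 0 lower stayed 0 under other scalings, filters, thresholds on the adjusted p, limma-voom and limma on the FPKM values. They were 66 and 3 in DESeq2, and 173 and 33 at an unadjusted p under 0.05 with at least 2-fold. With 1 library left out in edgeR they ranged from 0 to 7 higher and from 0 to 58 lower, all nonzero counts coming without OxtrTg replicate 4. In such fits the lone library of a genotype is assumed to vary like the other group. DESeq2 gave 44 to 82 higher and 2 to 421 lower with 1 library left out, and 25 genes of its 69, among them Cfd, Scd1, Eln, Cuzd1 and Zfp970, were called in all 5 of its fits. Oxtr, Gsg1l and Gm14403 were not. The 12 lists past camera became 0 with an estimated correlation and 0 with fry, and 2 of the 12, adipocyte and endothelial markers, held without each library in turn. Scaling moved the median log2 difference of all genes between -0.00335 (TMM) and -0.0152 (total counts). Of the named genes, 52 turned direction when 1 library was left out, with these ranges of the log2 difference: Prlr (-1.78 to 0.64), Stat3 (-0.0275 to 0.15), Socs3 (-0.18 to 0.24), Cish (-1.09 to 0.11), Lhcgr (-1.52 to 1.88), Fshr (-0.31 to 0.11), Amh (-0.36 to 0.56), Star (-2.44 to 0.16), Cyp11a1 (-2.89 to 0.93), Cyp17a1 (-1.81 to 0.63), Cyp19a1 (-0.59 to 2.50), Socs2 (-0.14 to 0.00794), Mcl1 (-0.12 to 0.0238), Esr1 (-1.02 to 0.59), Gja1 (-0.0837 to 0.29), Inha (-0.35 to 0.0225), Aldh1a1 (-1.68 to 0.18), Padi6 (-0.51 to 0.49), Nlrp14 (-0.26 to 0.57), Rgs2 (-0.13 to 0.46), Cited2 (-0.64 to 0.31), Ccnd2 (-0.28 to 0.19), Clu (-0.69 to 0.29), Lyz2 (-0.0389 to 0.93), Mpeg1 (-0.35 to 0.12), Cd4 (-1.43 to 0.66), S100a9 (-3.38 to 1.24), Nos2 (-0.35 to 0.30), Bst2 (-0.37 to 0.0331), Stat2 (-0.18 to 0.0687), Acta2 (-0.54 to 0.57), Myh11 (-0.69 to 0.66), Krt19 (-0.36 to 1.23), Ovgp1 (-6.33 to 1.15), Dnah5 (-7.52 to 0.18), Bpgm (-0.56 to 0.20), Jun (-0.60 to 0.27), Egr1 (-0.27 to 0.78), mt-Co1 (-0.0914 to 0.25), mt-Cytb (-0.13 to 0.22), Scd2 (-0.55 to 0.0679), Sfrp4 (-4.41 to 0.61), Ptgfr (-4.87 to 0.15), Rxfp1 (-1.74 to 3.09), Acadm (-0.21 to 0.38), Cidea (-6.37 to 0.73), Cpt1a (-0.50 to 0.34), Hadha (-0.49 to 0.26), Plin4 (-0.12 to 1.91), Gpam (-0.65 to 0.32), Rad18 (-0.0934 to 0.0906), Spag17 (-6.57 to 0.20). By another setting, Lhcgr turned to 0.15 with limma-voom, 0.0937 with FPKM and 0.140 with a pseudocount of 0.1. Padi6 turned to -0.00621, -0.0155 and -0.0171 in the same 3, and Nos2 to -0.0102, -0.0199 and -0.0217, and to -0.00256 without a filter. Ovgp1 turned to -0.0293 with total counts, -0.0132 with the upper quartile, -2.39 with limma-voom, and -2.28 and -2.40 with FPKM. Rad18, at 0.00195 in edgeR with TMM, turned to -0.00424 with DESeq2 size factors, -0.00913 with total counts, -0.00876 with the upper quartile, -0.00429 in DESeq2, -0.0104 without a filter, and -0.00775 and -0.0102 with FPKM. For these genes, FPKM values without the filter gave the values of those with it. Lists that turned direction with 1 library left out had these ranges of the camera adjusted p: oxytocin and prolactin signalling (0.37 to 0.767), STAT3 response (0.149 to 0.804), steroid hormone synthesis (2.3e-13 to 0.19), hormone receptors (0.0283 to 0.744), granulosa cell markers (0.322 to 0.666), theca and interstitial cell markers (1.1e-05 to 0.76), luteal cell markers (6.1e-18 to 0.162), oocyte markers (2.4e-13 to 0.901), ovulation and cumulus expansion (0.149 to 0.783), cell cycle (1.6e-06 to 0.744), apoptosis and atresia (0.187 to 0.962), lymphocyte markers (1.1e-08 to 0.827), neutrophil markers (0.0046 to 0.216), cytokines and chemokines (0.0152 to 0.209), smooth muscle markers (5.4e-05 to 0.909), surface epithelium markers (7.1e-04 to 0.76), oviduct epithelium markers (1.3e-16 to 0.442), immediate early genes (0.00203 to 0.981), mitochondrially encoded genes (0.149 to 0.708). Neutrophil markers turned with fry (0.998) and DESeq2 size factors (0.969), and cytokines with fry (0.998). For every result that changed, the cause was not tested.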

Other observations

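The tests in this part were chosen after the result was seen, except the second adipocyte list and the second list of ciliated cell genes, whose bounds were set before their values were looked at. Among the 64 genes that DESeq2 called higher in OxtrTg and that carry a biological process term in the deposited table, 25 of 2744 terms were over-represented against the 14724 tested genes with a term (hypergeometric test, adjusted p under 0.05). This test treats genes as independent, while the adipocyte markers had an estimated inter-gene correlation of 0.395. Its p-values may thus be too small. The first terms given here also share genes, among them Adipoq, Cav1, Cd36, Fabp4 and Scd1. The smallest adjusted p were those of response to bacterium (13 genes, among them Adipoq, Cfd, Fabp4 and Lpl, with 0.643 expected, adjusted p = 1.5e-10) and positive regulation of cold-induced thermogenesis (10 genes, among them Oxtr, with 0.326 expected, adjusted p = 1.1e-09). Other terms included triglyceride biosynthesis (4 genes, Acsl1, Dgat2, Lpl and Pnpla3, with 0.0696 expected, adjusted p = 3.9e-04), elastic fibre assembly (Fbln5, Lox and Ltbp4, adjusted p = 0.00653) and collagen fibril organisation (Adamts12, Dpt, Lox and Lum, adjusted p = 0.0115). Eln, the gene of elastin, was at 321 ± 71.2 CPM in OxtrTg and 135 ± 5.28 in WT (SD, n = 2 each), and Spon1 at 364 ± 26.8 against 161 ± 20.2. Pcx and Pck1, enzymes of glucose and glycerol synthesis, were at 168 ± 12.6 against 84.7 ± 1.26 CPM and at 83.5 ± 27.0 against 7.88 ± 3.33. Gapdh, often used as a reference gene, was also among DESeq2's calls (57.9 ± 7.67 against 30.0 ± 4.21 CPM, DESeq2 adjusted p = 0.0374). The Gapdh call was not kept in every DESeq2 fit that left a library out. In edgeR none of these genes passed over all genes.

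Only 5 of 15311 tested genes had at most 3 counts over both libraries of one genotype and at least 2 CPM in both libraries of the other. They were Cuzd1, Mup9 and Pou3f3, present in OxtrTg, and Zfp970 and Gm14403, present in WT. Cuzd1, on chromosome 7 from 130910283 to 130924021, had 191 and 235 counts in OxtrTg and 0 in WT, at least 153-fold higher with a floor of 3 counts over the group. Mup9, a member of the major urinary protein family whose near-identical copies can share reads, had 91 against 0 counts, at least 32.7-fold higher. The other pairings of the 4 libraries gave 2 and 1 such genes. The labels give no strain, so a difference of strain background between the genotypes was not tested and stays open for these genes. On chromosome 6 the neighbours of Oxtr were close in level, with Rad18 at 18.7 CPM in both genotypes and Lmcd1 at 33.0 against 26.4, and Cav3 had 3 to 8 counts per library. Single libraries held further genes of their own. Rxfp1, the relaxin receptor, was at 114 CPM in OxtrTg replicate 4 and 4.02 to 14.0 in the others, and the T cell gene Cd3g was at 11.2 CPM in WT replicate 5 and 1.07 to 3.04 in the others.

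Adipocyte markers were higher in both OxtrTg libraries. Trimming that also removed the oviduct from OxtrTg replicate 3 would not by itself account for OxtrTg replicate 4. There the adipocyte list had a median log2 difference of 2.72 from the WT mean although oviduct markers were at the WT level. That value was known when the pattern was picked, so it is no separate test of trimming. More fat cells in the OxtrTg tissue stays open as a candidate explanation: a second list of 12 adipocyte genes had a median log2 difference from the WT mean of 0.713 in the lower OxtrTg library (quartiles 0.119 and 1.93), between the bounds of 0.5 and 1 set before, with Aqp7 at 6.48 and 4.74 CPM against 1.01 and 0.251 but Gpam at 352 and 474 against 331 and 643. Whether fat around the ovary was dissected differently or the genotype itself changed it cannot be told apart, since 2 libraries per genotype carry both, and an RNA protocol naming adipose tissue applies to all 4 libraries alike.

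Oviduct transcripts were low in OxtrTg replicate 3. Genotype as a cause shared by both OxtrTg libraries is argued against by OxtrTg replicate 4, whose oviduct list had a median log2 difference of 0.138 from the WT mean. That value was known when the pattern was picked, so it is no separate test of genotype. Shallow sequencing is argued against by the total count of OxtrTg replicate 3, which was 0.953 times the mean of the other 3 libraries. A lack of oviduct tissue in that library may account for the pattern: a second list of 12 ciliated cell genes had a median log2 difference of -3.21 from the other 3 libraries, past the bound of -2 set before. Spag17 and Dynlrb2 in the first list were at 0.13 CPM there, and 752 genes lay over 2-fold below all other libraries in it, against 75 to 230 in the other libraries.

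Luteal transcripts were high in WT replicate 6. Genotype as a cause shared by both WT libraries is argued against by WT replicate 5, whose luteal list lay at a median log2 difference of -0.0979 from the OxtrTg mean. That value was known when the pattern was picked, so it is no separate test of genotype. More luteal tissue in WT replicate 6 is a candidate explanation: a second list of 6 genes of cholesterol handling had a median log2 difference of 0.568 from the other 3 libraries. Its quartiles were 0.0979 and 1.30, with Hsd17b7 at 73.4 CPM against 21.3 to 26.5 but Npc1 at 43.4 against 40.4 to 46.8, and 3 of its 6 genes are also on the fixed lists. The luteal genes Sfrp4 (727 CPM against 22.6 to 38.2) and Ptgfr (316 against 5.63 to 23.6) set the same library apart.

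For DESeq2's 69 calls, the 4 libraries have 3 splits into 2 and 2, too few to give a share under 0.05. Of these, 2 gave at least 69 calls, the real split included, and the highest other split gave 262. That split pairs OxtrTg replicate 3 with WT replicate 6 and points to a structure of the libraries other than genotype. It called 0 adipocyte markers against 11 in the real split. Each of its sides holds 1 library of each genotype, so genes that separate the genotypes could hardly be called there. The 0 therefore does not favour the real split. In edgeR each of the 3 splits gave 0 calls. The 393 genes of the real split at an unadjusted p under 0.05 in edgeR are fewer than the 766 expected by chance. That count was not taken for the other splits, so it does not set the real split apart.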
